A study of Mus musculus with 50 samples.

How the data were processed

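Single cells from the mammary fat pad or tumour of BALB/c female mice, or from their lung metastases, were profiled by MARS-seq, a plate-based method that tags the 3′ end of polyadenylated RNA with a cell barcode and a unique molecular identifier (UMI). The tissues sampled were, per the labels: naive mammary fat pad (NMF), tumours 2 weeks (2W) and 4 weeks (4W) after injection of 4T1-luc cells into the fat pad, and lung metastases (Met) at 5 weeks. 4T1-luc is a luciferase-marked line of the BALB/c mammary carcinoma 4T1. The mice with metastases had their primary tumour removed at 2 weeks, per the labels' protocols. Cells were sorted as propidium iodide, Ter119, CD45 and EpCAM negative, a gate meant to leave out dead, erythroid, immune and epithelial cells. Fat pads were digested with collagenases II and IV in a mechanical dissociator, tumours with collagenase A and pipetting, and metastases with collagenase A and dispase II in the dissociator, so tissue preparation differed between groups. Mouse age followed the group, per the labels: 8 weeks for NMF, 10 for 2W, 12 for 4W and 13 for Met.

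The deposited files hold raw counts of molecules per gene and well for 50 plates of 384 wells, with no normalization, per the labels and the values themselves. The submitters' processing notes name bcl2fastq 2.15.0.4 and the mm10 genome; the aligner, the counting program and the annotation are not given in the sources used here. A deposited table of the series gives the plate, the replicate and the fluorescence intensity of each well from the index sort, in arbitrary linear units that can fall below 0. The channel that recorded podoplanin (PDPN) was APC-Cy7 in NMF, 2W, 4W replicates 2 to 6 and Met replicate 1, and APC in Met replicates 2 and 3; 4W replicate 1 had no record. The replicate identifier in the labels was the unit of replication: 3 for NMF, 3 for 2W, 6 for 4W and 3 for Met, 15 in all. The labels do not say whether an identifier stands for 1 mouse or a pool, so the p-values measure the spread between these identifiers.

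Genes were used under the symbols in the files (33924 without the ERCC spike-in rows). ERCC molecules made up 3.51% of the counts in kept wells and were left out. Of 19200 wells, 200 were labelled as holding no cell and 6694 others had under 500 UMIs; the remaining 12306 were kept. An upper limit of 20% mitochondrial UMIs removed nothing, since no well had such a UMI. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (seed 7) gave 27 clusters, without batch integration. A cluster took the name of the cell type with the most fixed markers among its 10 leading genes by fold, ties going to the higher mean fold, if at least 3 markers were raised and seen in 10% of its cells. Clusters 12 and 14 stayed unnamed. The classes below are therefore fibroblast-like, epithelial-like or carcinoma-like (called carcinoma-like), endothelial-like, pericyte-like or smooth muscle-like, immune-like, erythroid-like and skeletal muscle-like. They are rebuilt from the counts and may differ from the authors' own assignments. No doublet caller was run; leaving out the top 1% of wells by UMIs was tried instead.

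Kept UMIs per replicate ranged from 1351960 to 7460477, and the median per kept cell from 1243 to 6378. Counts were summed per replicate over the cells of the fibroblast-like class, over all kept cells and, in an analysis chosen after seeing the data, over the carcinoma-like class. A replicate needed 20 cells to enter, which left out 4W replicate 1 (19 fibroblast-like cells) from the fibroblast-like sums. In those sums 4W replicate 4 entered with 22 cells (93637 UMIs) and Met replicate 2 with 36 (41778 UMIs, TMM factor 1.41). The largest, of 2W replicate 2, held 2505135 UMIs, so levels in these 2 small sums rest on few counts. Replicates of a group differed by more than sampling noise in every pair. The main test was edgeR's quasi-likelihood F test with TMM normalization, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05, fitted to the 4 groups together. Levels of genes are CPM (molecule counts scaled to a common library size) with TMM scaling, as mean ± SD over replicates, unless they are called unscaled. Where a gene had no count in a group, the fold is a lower bound computed from 3 counts over the group; with 1 to 3 counts, the ratio of pooled counts is given with its exact 95% interval, which covers counting error only. Among 200 simulated changes per contrast, the test recovered 34% (2W against NMF), 38% (4W against NMF), 32% (4W against 2W) and 15% (Met against 4W) of those of log2 size 1 in the fibroblast-like class, and 92%, 91%, 85% and 70% of those of size 2, with at most 9 false calls.

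The fixed gene lists were tested with camera from limma (preset correlation 0.01), beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the lists. Fixed markers of other cell types were tested in the same way as a second family. Class shares, the log2 ratio of S100a4 to Pdpn counts (1 count added to each) and the replicate medians of PDPN intensity were compared by two-sided exact permutation tests over replicates. Shares of cells with a UMI were also computed after thinning each cell to 500 UMIs. The genes named for each contrast of the fibroblast-like class are the 8 largest rises and 8 largest falls with an adjusted p under 0.05, an absolute log2 change of at least 1, no overlap between the replicates of the groups and a mean of at least 100 CPM in the higher group; clone-style names were left out. To these come the 2 members of smallest p of each list that passed, and 12 marker genes of the study's subject. For sums of all cells and of the carcinoma-like class the limits were 5 and 5. The groups, tests, lists, markers, naming rule and first set of alternatives were fixed before the data were examined. Any gene named outside the rule is given as an example of its list, or was chosen after its values were seen. The result of 1 gene is not reported here.

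The alternatives were median-of-ratios size factors, no filter on low counts, the replicate number as a block, a fit of only the groups compared, the DESeq2 Wald test, 1000 UMIs per well, the top 1% of wells left out, resolutions 0.5 and 2, no mitochondrial limit, leaving out each replicate in turn, and 4W replicates of the 2W sequencing batch alone. For the ratio, the fibroblast-like class alone and thinned shares were added. Chosen after seeing the data were fibroblast-like cells with no Krt8, Krt18, Wfdc2 or Epcam UMI, and the class without clusters found in 1 replicate. The sequencing batch, as the deposited table gives it, was shared between groups only by the 2W replicates and 4W replicates 3 to 6; every other contrast is confounded with batch, and every contrast with mouse age. Gene coordinates come from GENCODE annotation of GRCm38, the assembly also called mm10. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.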

Results

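The data describe 12306 single cells from the sorted stromal fraction of naive mammary fat pad (NMF, 3 replicates, 2637 cells), tumours at 2 weeks (2W, 3 replicates, 2131 cells), tumours at 4 weeks (4W, 6 replicates, 5205 cells) and lung metastases (Met, 3 replicates, 2333 cells). The replicate identifier of the labels was the unit. Kept UMIs per replicate were 1392961 to 1563749 in NMF, 1788861 to 3840947 in 2W, 1899104 to 7460477 in 4W and 1351960 to 2283643 in Met. The median per cell ran from 1243 to 1473 in NMF, 1998 to 4489 in 2W, 1877.5 to 6378 in 4W and 1377 to 1991 in Met. The 27 clusters gave a fibroblast-like class of 5442 cells, carrying Col1a1, Col3a1, Dcn and Lum, and a carcinoma-like class of 5140 cells, carrying Krt8, Krt18, Krt7 and Wfdc2. The other named classes were endothelial-like (752 cells), pericyte-like or smooth muscle-like (243), immune-like (88), skeletal muscle-like (41) and erythroid-like (28). A further 572 cells in 2 clusters stayed unnamed.

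The make-up of the stromal fraction was compared across the course of the tumour. Fibroblast-like cells made up 93.4% ± 3.05 (SD, n = 3) of kept cells in naive fat pad, 67.3% ± 6.94 (n = 3) in 2W tumours, 17.3% ± 12.5 (n = 6) in 4W tumours and 19.2% ± 14.2 (n = 3) in metastases. Carcinoma-like cells, which carry keratins of simple epithelia, moved the other way, from 0.227% ± 0.197 in fat pad to 28.0% ± 6.07 at 2W, 69.8% ± 13.7 at 4W and 47.1% ± 28.8 in metastases. Endothelial-like cells, marked by Pecam1 and Cdh5, made up 3.23% ± 1.82, 1.75% ± 0.637, 8.00% ± 4.10 and 7.62% ± 2.17 in the same order. Unnamed cells made up 21.1% ± 13.5 of metastases and 2.03% ± 4.69 of 4W tumours. Of these, cluster 12, with the endothelial genes Ptprb, Vwf and Plvap among its leading genes but too few fixed markers for a name, made up 13.5% ± 4.45 of metastases and 0.0280% ± 0.0686 of 4W tumours. It is not counted in the endothelial-like share.

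Between 4W and 2W the fibroblast-like share fell by 50.1 percentage points (two-sided exact permutation p = 0.0119, the smallest that 6 against 3 allows; adjusted p = 0.0476 over 8 classes). Within the sequencing batch that both groups share it fell by 50.6 points (4 against 3, exact p = 0.0286). Against fat pad the 4W share fell by 76.1 points (exact p = 0.0119, adjusted p = 0.0476). The carcinoma-like share rose by 41.8 points from 2W to 4W and by 69.5 points from fat pad to 4W (exact p = 0.0119 and adjusted p = 0.0476 for each). For 2W against fat pad the fibroblast-like difference was -26.0 points and the carcinoma-like difference 27.7 points, both with an exact p of 0.1, the smallest that 3 against 3 allows. Between metastases and 4W tumours the fibroblast-like difference was 1.95 points (exact p = 0.786; -4.48 without Met replicate 3 and 9.54 without Met replicate 2) and the carcinoma-like difference -22.7 points (p = 0.143), within the spread of replicates. The endothelial-like difference of 6.25 points between 4W and 2W had an exact p of 0.0476 and an adjusted p of 0.127. The unnamed share was 19.1 points higher in metastases than at 4W (exact p = 0.0238, adjusted p = 0.190). The gate removes EpCAM-positive and CD45-positive cells, so these are shares of what passed it and the UMI minimum, not of the tissue. That minimum kept unequal parts: 5205 wells of 25 plates at 4W, 2131 of 7 at 2W and 2637 of 9 in fat pad. In 4W replicates 2 to 6, fibroblast-like cells had a lower median of UMIs than other kept cells. In 4W replicate 1 it was higher. Loss of fibroblast-like wells under the minimum could add to the fall at 4W, which was not tested. The fibroblast-like share was 33.6% in 4W replicate 2, where 1905 of 2304 wells were kept.

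**Figure D1:**
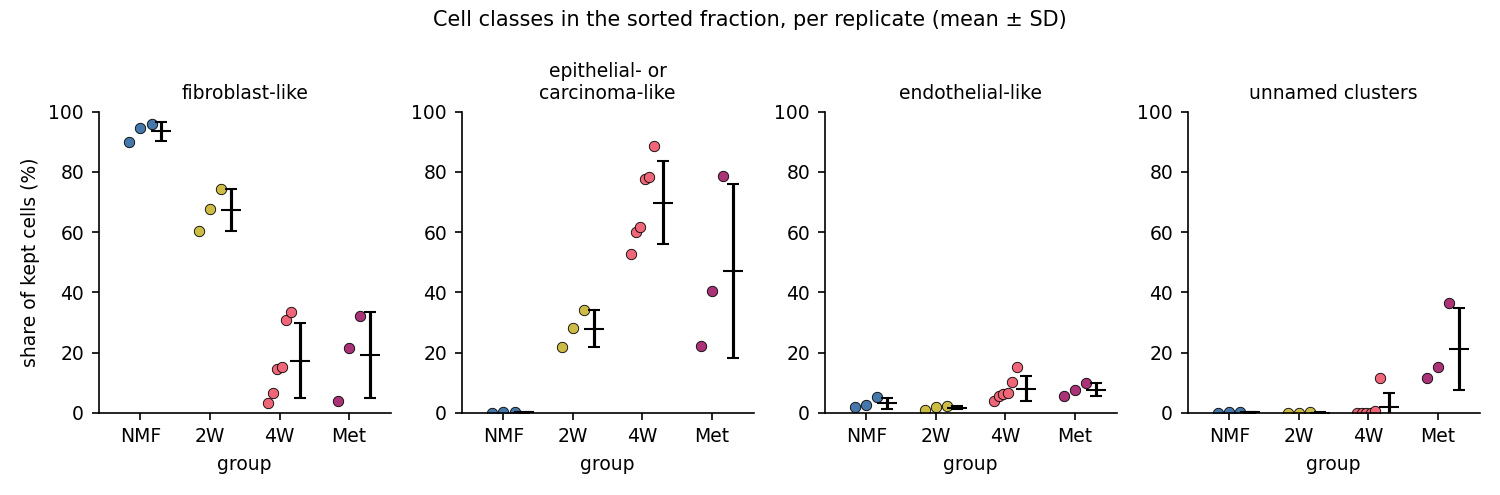
Share of kept cells (percent, linear axis from 0) that were fibroblast-like, carcinoma-like, endothelial-like or unnamed, per replicate. Groups are naive fat pad, 2W and 4W tumours and lung metastases. Points are replicates and black marks the mean ± SD. The fibroblast-like share falls from a mean of 93.4% in fat pad to 17.3% at 4W while the carcinoma-like share rises from 0.227% to 69.8%.

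S100a4 and Pdpn, which mark subsets of stromal cells in this study, were compared next. S100a4 (GRCm38 chromosome 3, 90603771 to 90606045, plus strand) encodes a calcium-binding protein of motile cells, and Pdpn (chromosome 4, 143267431 to 143299564, minus strand) a surface glycoprotein, podoplanin. Over all kept cells the log2 ratio of S100a4 to Pdpn counts was -2.08 ± 0.218 in fat pad (SD, n = 3), 1.57 ± 0.535 at 2W (n = 3), 4.10 ± 0.907 at 4W (n = 6) and 5.16 ± 4.47 in metastases (n = 3). It rose by 2.53 from 2W to 4W (exact permutation p = 0.0119) and by 2.87 within the shared sequencing batch (exact p = 0.0286). From fat pad to 4W it rose by 6.18 (exact p = 0.0119). The differences of 3.65 between 2W and fat pad (exact p = 0.1, the smallest possible) and of 1.06 between metastases and 4W (exact p = 0.571) did not pass. The latter was -1.17 without Met replicate 2 and 3.301 without Met replicate 1.

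Within the fibroblast-like class alone the ratio was -2.10 ± 0.207 in fat pad, -0.78 ± 0.135 at 2W, -0.86 ± 0.340 at 4W (n = 5) and -0.03 ± 2.28 in metastases. There it rose by 1.25 from fat pad to 4W (exact p = 0.0179), while the change from 2W to 4W was -0.08 (exact p = 0.75), opposite in sign to that of all cells. Unscaled S100a4 CPM was 82.4 ± 12.3, 326 ± 41.0, 342 ± 148 and 208 ± 173 in the fibroblast-like class (fat pad, 2W, 4W, metastases). In the carcinoma-like class S100a4 was 2505 ± 335, 1716 ± 527 and 3552 ± 2280 (2W, 4W, metastases). Unscaled Pdpn CPM was 356 ± 42.8, 559 ± 50.2, 594 ± 115 and 201 ± 133 in the fibroblast-like class. In the carcinoma-like class Pdpn was 27.1 ± 1.94, 10.6 ± 5.62 and 29.5 ± 49.2. After thinning to 500 UMIs per cell, 57.3% ± 4.35 of carcinoma-like cells at 2W and 41.3% ± 10.3 at 4W had an S100a4 UMI, against 15.8% ± 2.88 and 15.1% ± 6.50 of fibroblast-like cells. Unthinned, these shares were 87.0% ± 5.84 and 77.0% ± 7.56 against 50.8% ± 9.31 and 38.5% ± 3.36. In endothelial-like cells at 4W, 7.07% ± 4.94 had an S100a4 UMI after thinning (n = 5).

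**Figure D2:**
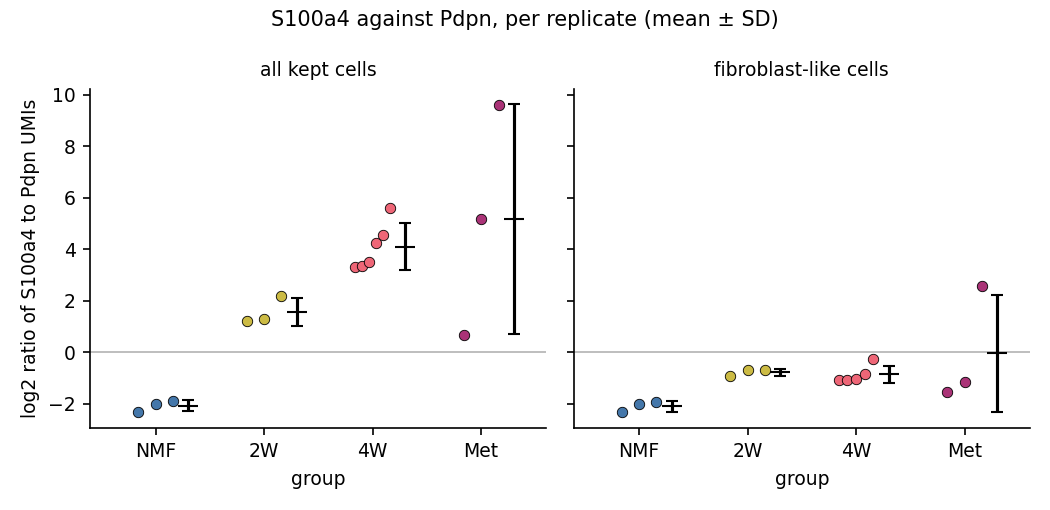
Log2 ratio of S100a4 to Pdpn counts per replicate, over all kept cells and over the fibroblast-like class alone, by group; points are replicates and black marks the mean ± SD. Over all cells the mean rises from -2.08 in fat pad to 4.10 at 4W, whereas in the fibroblast-like class it is -0.78 at 2W and -0.86 at 4W.

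Podoplanin protein on the sorted cells was read from the index sort. Over all kept cells the replicate medians of PDPN intensity averaged 4865 ± 445 arbitrary units in fat pad (SD, n = 3), 11130 ± 1888 at 2W (n = 3) and 94.9 ± 91.0 at 4W (n = 5). Carcinoma-like cells made up at least 52.8% of kept cells in every 4W replicate, so the 4W medians mostly reflect that class. The difference was -11035 between 4W and 2W (exact permutation p = 0.0179) and -11019 within the shared sequencing batch (exact p = 0.0286). Between 4W and fat pad it was -4770 (exact p = 0.0179). The difference of 6264 between 2W and fat pad had an exact p of 0.1, the smallest possible. Among fibroblast-like cells the medians ran from 4956 to 5322 in fat pad, 12242 to 19753 at 2W and 5196 to 52686 at 4W, and among carcinoma-like cells of the tumours from 7 to 117. Endothelial-like cells at 4W ranged from 20.5 in replicate 2 to 33342 in replicate 5. Their unscaled Pdpn was 14.1 ± 10.9 CPM, so in that class the intensity did not follow Pdpn RNA. In Met replicate 1, the only one recorded in the same channel, the median over all cells was 3378. It was 2669 in fibroblast-like and 6913 in endothelial-like cells of that replicate. Sort settings on different days were not calibrated against each other in the sources used here.

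**Figure D3:**
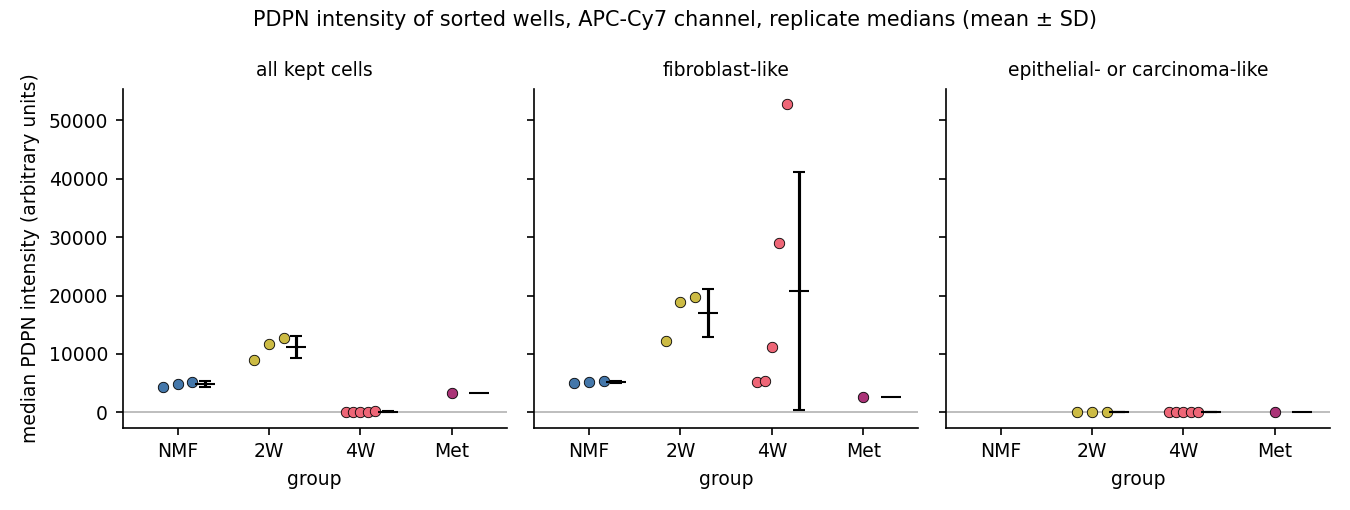
Median index-sort intensity of podoplanin (arbitrary units, APC-Cy7 channel) per replicate over all kept cells, fibroblast-like cells and carcinoma-like cells. Points are replicates and black marks the mean ± SD, with Met replicate 1 alone and no SD. Over all kept cells the 4W medians average 94.9, against 4865 in fat pad and 11130 at 2W. In fibroblast-like cells the 4W medians run from 5196 to 52686.

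Fibroblast-like cells of 2W tumours were compared with those of naive fat pad to ask how fibroblasts in an early tumour differ from resident ones. Spp1, the secreted matrix protein osteopontin (chromosome 5, 104435118 to 104441050, plus strand), reached 1617 ± 755 CPM at 2W (n = 3) with no count in fat pad (n = 3), at least 2299-fold higher. Saa3, an acute-phase serum amyloid (chromosome 7, 46711998 to 46715700, minus strand), reached 2730 ± 415 CPM against 0.497 ± 0.432, a ratio of 5329 (95% interval 1475 to 44000). Acta2, smooth muscle actin and a marker of myofibroblasts (chromosome 19, 34241090 to 34255590, minus strand), rose from 11.1 ± 6.76 to 1357 ± 368 CPM (log2 change 6.92, SE 0.657, adjusted p = 6.89e-08). The actin-severing gelsolin Gsn fell from 13297 to 898 ± 463 CPM (log2 change -3.89). Inmt, a methyltransferase (chromosome 6, 55170626 to 55175043, minus strand), fell from 923 ± 276 to 4.51 ± 5.60 (log2 change -7.96). Igf2, a growth factor (chromosome 7, 142650766 to 142666816, minus strand), fell from 179 ± 60.4 to 1.05 ± 1.12 CPM (log2 change -7.13).

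Of the contractile genes 10 of 11 rose over all genes tested and 10 adjusted over the list alone, with none lower. Among them were Tagln, Actn1 (226 ± 47.9 against 14.1 ± 2.82 CPM) and Actg2 (at least 168-fold). Their list had an adjusted p of 7.33e-15, and of 0.0346 with an estimated correlation. The inflammatory chemokines and cytokines rose in 16 of 17 members (16 adjusted over the list alone; list adjusted p = 7.33e-15, and 0.0346 with an estimated correlation). They included Ccl7 (664 ± 249 against 18.9 ± 9.79 CPM), Cxcl14 (4172 ± 1369 against 208 ± 23.2) and Cxcl5 (at least 129-fold). Lung fibroblast genes, a list fixed for the metastases, fell in 8 of 12 members (8 lower and 1 higher adjusted over the list alone; adjusted p = 9.54e-06, and 0.0346 with an estimated correlation), among them Inmt and the carboxylesterase Ces1d.

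Other lists passed with the preset correlation but not with an estimated one, whose adjusted p follows each. Fibrillar and interstitial matrix rose in 12 of 21 members and fell in 2 (15 and 2 adjusted over the list alone; adjusted p = 5.31e-07, then 0.119), with tenascin C (Tnc) at 566 ± 251 against 9.02 ± 3.83 CPM and Col12a1 at 460.5 ± 115 against 13.1 ± 2.62. Cell cycle genes rose in 15 of 18 (15 adjusted over the list alone; 3.99e-09, then 0.114), with Cdk1 at 68.5 ± 21.6 against 3.02 ± 2.66 CPM. Glycolysis and hypoxia genes rose in 12 of 17 (13 adjusted over the list alone; 9.95e-09, then 0.119), with hexokinase Hk2 at 59.9 ± 20.4 against 1.45 ± 0.1003 CPM. Growth factor and TGF-beta targets rose in 6 of 12 and fell in 1 (6 and 2 adjusted over the list alone; 4.96e-05, then 0.0973), with the activin subunit Inhba at log2 7.27 and Ctgf at log2 4.44. Dissociation stress genes rose in 9 of 17 and fell in 2 (13 and 2 adjusted over the list alone; 3.17e-05, then 0.218), and MHC class II genes rose in 4 of 5 (4 adjusted over the list alone; 0.00179, then 0.182). Unscaled Cd74 at 2W was 33.9 ± 6.06 CPM in fibroblast-like and 819 ± 525 in carcinoma-like cells. Resting fibroblast genes fell in 10 of 16 (10 adjusted over the list alone; 5.31e-07, then 0.179), with the guidance factor Sema3c at log2 -2.79. Basement membrane genes fell in 7 of 11 (7 adjusted over the list alone; 0.000561, then 0.182), lipid and adipogenic genes in 4 of 7 (4 adjusted over the list alone; 0.000584, then 0.114) and complement genes in 4 of 7 (4 adjusted over the list alone; 0.0223, then 0.296). The laminin Lama2 stood at log2 -3.26 and Apoe at -3.20. Not passing were MHC class I presentation (adjusted p = 0.329), interferon response (0.698), protein folding (0.139), matrix proteases and inhibitors (0.0987) and the study's marker genes (0.183).

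Among those markers S100a4 rose from 85.2 ± 13.1 to 365 ± 50.1 CPM (log2 change 2.10, adjusted p = 4.68e-05), Thy1 rose (0.92) and Itgb1 rose (0.77). Cd34 fell by 1.84, Fap by 1.08 and Ly6c1 by 0.98 on the log2 scale. Fap lost its call without NMF replicate 1 or 2W replicate 1 or 2, Itgb1 without NMF replicate 1 or 3 or 2W replicate 1 or 2, and Ly6c1 without NMF replicate 1, 2 or 3 or 2W replicate 1 or 2. Pdpn stood at 624 ± 48.1 against 368 ± 45.3 CPM (adjusted p = 0.0704). Epithelial markers were measurable beside these groups: Krt18, Krt7, Krt8 and Wfdc2, 4 of 5 measured, rose and Krt19 fell. Unscaled Krt18 was 96.1 ± 72.1 CPM in fibroblast-like cells at 2W, 1203 ± 200 in carcinoma-like and 253 in endothelial-like cells of 1 replicate.

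Of 10057 genes tested with edgeR, 1363 were higher and 1432 lower at 2W (adjusted p under 0.05); leaving out 2W replicate 2 gave 1744 in all. With any 1 replicate left out more genes were higher than lower (952 and 792 without 2W replicate 2). The class came from different clusters in the groups, clusters 1, 7, 16, 17 and 18 in fat pad and 8, 5 and 2 at 2W. Sequencing batch, enzymes and mouse age also differed between them and cannot be told apart from the group. Saa3, Reg3g and Reg1 belong to multigene families, and how reads shared between copies were counted is not given in the sources used here.

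Fibroblast-like cells of 4W tumours were also compared with those of naive fat pad. Spp1 reached 1789 ± 463 CPM (n = 5) against no count in fat pad (n = 3), at least 2652-fold higher. Inhba rose from 0.974 ± 1.09 to 195 ± 84.2 CPM (log2 change 7.52, SE 0.618, adjusted p = 1.55e-08). The transcription factor Runx1 rose from 1.99 ± 1.68 to 183 ± 28.2 (6.49), the actin-binding Tagln from 7.41 ± 2.96 to 684 ± 438 (6.53) and Acta2 to 996 ± 466 (6.49). Falls were led by Inmt (6.48 ± 13.2 against 923 ± 276 CPM, log2 change -6.09), the sulfotransferase Sult1a1 (-6.60), the circadian-output factor Hlf (-5.55), Igf2 (-5.35), the secretory-granule protein Scg3 (-5.17), Galntl2 (-4.77) and the adhesion molecule Opcml (-4.72). The embryonic globin Hbb-y, from a multigene cluster, had no count at 4W and 124 ± 103 CPM in fat pad, at least 110-fold lower. Krt18 (133 ± 76.5 against 1.22 ± 0.474 CPM) and Wfdc2 (124 ± 117 against 0.736 ± 0.716; ratio 176, 95% interval 59.6 to 856) were also among the 8 largest rises. Both are epithelial markers, and in endothelial-like cells at 4W unscaled Krt18 was 162 ± 127 and Wfdc2 102 ± 99.9 CPM.

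Contractile genes rose in 10 of 11 members (10 adjusted over the list alone; list adjusted p = 1.33e-12, and 0.0761 with an estimated correlation). In the other lists that passed, the second p again uses an estimated correlation, and none passed with it. Glycolysis and hypoxia rose in 13 of 17 (13 adjusted over the list alone; adjusted p = 3.08e-09, then 0.113) and inflammatory chemokines and cytokines in 10 of 17 (11 adjusted over the list alone; 1.37e-07, then 0.113). Fibrillar and interstitial matrix rose in 11 of 21 (13 adjusted over the list alone; 2.5e-07, then 0.113) and cell cycle in 13 of 18 (13 adjusted over the list alone; 8.69e-07, then 0.144). Ccl2, a monocyte attractant, stood at 455 ± 258 against 9.25 ± 3.45 CPM, Tnc at 654 ± 289 against 9.02 ± 3.83 and the glycolytic Pgk1 at 450 ± 60.5 against 72.6 ± 0.295. Growth factor and TGF-beta targets rose in 7 of 12 and fell in 1 (the same counts adjusted over the list alone; 2.9e-05, then 0.0828). MHC class II rose in 4 of 5 (4 adjusted over the list alone; 0.000589, then 0.144). Unscaled Cd74 at 4W was 46.8 ± 34.0 CPM in fibroblast-like and 733 ± 318 in carcinoma-like cells, and H2-Aa 27.5 ± 21.5 and 429 ± 251. Protein folding rose in 5 of 19 with 1 lower (7 and 2 adjusted over the list alone; 0.0246, then 0.488). Resting fibroblast genes fell in 13 of 16 (14 adjusted over the list alone; 3.2e-07, then 0.144), basement membrane in 8 of 11 (8 adjusted over the list alone; 0.000442, then 0.144) and complement in 6 of 7 (6 adjusted over the list alone; 0.00109, then 0.144). Lipid and adipogenic genes fell in 6 of 7 (6 adjusted over the list alone; 2.39e-05, then 0.0761) and interferon response in 6 of 18 (6 adjusted over the list alone; 0.0246, then 0.488). Lung fibroblast genes fell in 7 of 12 and rose in 2 (8 and 2 adjusted over the list alone; 0.00011, then 0.0761). Gsn stood at 700.1 ± 282 against 13297 CPM, Efemp1 at log2 -2.15, Lama2 at -2.94, C1s at -1.38, Apoe at -3.86 and Irf7, an interferon regulator, at -1.69. Dissociation stress (adjusted p = 0.2), MHC class I presentation (0.597), matrix proteases and inhibitors (0.381) and the study's marker genes (0.185) did not pass; among these markers S100a4 rose by 2.06 and Vim by 0.72 on the log2 scale, and Cd34 (-1.90), Ly6c1 (-1.32), Fap (-1.21) and Pdgfra (-0.79) fell. Pdgfra lost its call without NMF replicate 1, 2 or 3 or 4W replicate 2, 3 or 6, and Vim without NMF replicate 1 or 2 or 4W replicate 3, 5 or 6.

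Of 10057 genes, edgeR called 1286 higher and 1398 lower at 4W, and more higher than lower without NMF replicate 1, 2 or 3 or 4W replicate 2, 3, 4 or 6 (1390 and 1306 without 4W replicate 4). The protein folding list lost its call without 4W replicate 4 (adjusted p = 0.0572), at 1000 UMIs per well (0.0509) and without cells holding a Krt8, Krt18, Wfdc2 or Epcam UMI (0.0727), and the interferon list in the last setting too (0.161). The class came from clusters 2, 5 and 8 at 4W, and batch, enzymes and mouse age again differ with the group and cannot be told apart from it.

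Fibroblast-like cells were compared between 4W and 2W tumours. Fosb, a subunit of the AP-1 transcription factor (chromosome 7, 19302696 to 19310051, minus strand), fell from 684 ± 435 CPM (n = 3) to 74.8 ± 39.6 (n = 5; log2 change -3.05, SE 0.366, adjusted p = 0.000249). Atf3 (-2.97), Btg2 (-2.73), Nr4a1 (-2.32), Nfkbia (-2.15), Zfp36 (-2.06) and Phlda1 (-1.78), all genes induced within minutes to hours of stimulation, fell as well. Reg3g, a secreted lectin, fell from 582 ± 279 to 47.4 ± 50.5 CPM (-3.20), the chemokine Cxcl12 from 1452.5 ± 325 to 439 ± 126 (-1.73, adjusted p = 0.0026) and Irf7 from 227 ± 14.3 to 66.5 ± 40.3 (-1.65, adjusted p = 0.0088). Wnt9a, a secreted signalling protein, was the only gene to rise, from 33.8 ± 3.31 to 114 ± 32.6 CPM (1.64, adjusted p = 0.00295).

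Dissociation stress genes fell in 10 of 17 members (15 adjusted over the list alone), with a list adjusted p of 9.02e-29, and of 0.0355 with an estimated correlation. The inflammatory list passed with the preset correlation (1 of 17 lower over all genes, 8 adjusted over the list alone; adjusted p = 3.95e-10), with an adjusted p of 0.153 under an estimated correlation. Il6 stood at 38.4 ± 15.5 against 158 ± 120.5 CPM (adjusted p = 0.056). Interferon response passed likewise (1 of 18 lower, 6 adjusted over the list alone; 9.55e-08, and 0.382 with an estimated correlation), with Isg15 at 74.5 ± 35.3 against 201 ± 16.2 CPM (adjusted p = 0.0564). MHC class I presentation (0.0111, then 0.535 with an estimated correlation; 1 lower of 10 adjusted over the list alone), complement (0.0226, then 0.532; 2 lower of 7) and lipid and adipogenic genes (0.0226, then 0.417; 2 lower and 1 higher of 7) passed without a member called over all genes. Contractile genes (adjusted p = 0.198), fibrillar and interstitial matrix (0.523), resting fibroblast genes (0.523), basement membrane (0.556), cell cycle (0.0776), glycolysis and hypoxia (0.198), growth factor and TGF-beta targets (0.796), protein folding (0.161), MHC class II (0.278), matrix proteases and inhibitors (0.0776) and lung fibroblast genes (0.605) did not pass. None of the 12 study markers passed. Acta2 stood at 996 ± 466 against 1357 ± 368 CPM, S100a4 at 349 ± 157 against 365 ± 50.1 and Pdpn at 605 ± 133 against 624 ± 48.1.

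In all, 1 gene was higher and 36 were lower of 10057 (edgeR, 668 with an unadjusted p under 0.05). Within the shared sequencing batch 20 genes passed, each of them among the 37. The count was 23 without 2W replicate 2, 21 without 2W replicate 3, 20 without 4W replicate 2, 59 with DESeq2, 70 with only these groups fitted and 182 with no filter on low counts. Phlda1 (log2 change -1.32) and Zfp36 (-1.49) lost their calls without 2W replicate 3. Phlda1 and Irf7 lost theirs without 4W replicate 2, the same fit as the shared batch, and Reg3g under DESeq2. The lipid list lost its call without 2W replicate 1, 2 or 3 or 4W replicate 3 or 6 (adjusted p 0.0647 to 0.501) and with no filter on low counts (0.193), and turned upward with the top 1% of wells left out (0.84). The complement list lost its call without 4W replicate 6 (0.203), without the top 1% of wells (0.25) and with no filter on low counts (0.0594). Without cells holding a Krt8, Krt18, Wfdc2 or Epcam UMI, complement (0.0955), MHC class I presentation (0.0693) and Wnt9a lost their calls. Clusters 8, 5 and 2 held the class at 2W and clusters 2, 5 and 8 at 4W, in that order of size. Mouse age differed between 2W and 4W within the shared batch too.

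Fibroblast-like cells of lung metastases were set against those of 4W primary tumours. Tcf21, a transcription factor of lung and other visceral mesenchyme (chromosome 10, 22817281 to 22820174, minus strand), reached 198 ± 86.8 CPM in metastases (n = 3) with no count at 4W (n = 5), at least 147-fold higher. Inmt stood at 3683 ± 1659 against 6.48 ± 13.2 CPM (log2 change 8.07, SE 0.612, adjusted p = 4.09e-09), Ces1d at 290 ± 60.8 against 0.245 ± 0.549 (ratio 402, 95% interval 110 to 3343) and the monooxygenase Fmo2 at 1628 ± 1507 against 4.12 ± 4.36 (7.78). Tbx4, which patterns lung mesenchyme, Gsta3, Wif1 and Ppp1r14a rose as well. Cthrc1, a secreted protein of activated fibroblasts (chromosome 15, 39076932 to 39087121, plus strand), fell from 720 ± 161 to 14.02 ± 16.01 CPM (log2 change -5.16, adjusted p = 4.09e-09). Lrrc15 fell from 364 ± 133 to 0.807 ± 1.398 CPM (ratio 319, 95% interval 57.2 to 12620), Adam12 by 4.22, Bcat1 by 4.18, Emb by 4.21 and Ddah1 by 4.12 on the log2 scale. Stra6 was lower by a ratio of 20.8 (95% interval 7.01 to 101) and Crabp1 at least 63.95-fold.

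Lung fibroblast genes rose in 10 of 12 members and Wnt2 fell (11 and 1 adjusted over the list alone; list adjusted p = 1.11e-13, and 0.00186 with an estimated correlation). Most members of this list were also lower at 4W than in fat pad. Cluster 16, with Inmt and Fmo2 among its leading genes, held 171 cells of fat pad, so the rise is not by itself a sign of lung origin. All 17 dissociation stress genes rose (17 adjusted over the list alone; 1.21e-18, and 0.0689 with an estimated correlation), with Fosb at 2271 ± 438 against 74.8 ± 39.6 CPM and Nr4a1 at 1031 ± 186 against 40.6 ± 18.6. Fibrillar and interstitial matrix fell in 14 of 21 (16 adjusted over the list alone; 2.86e-07, and 0.241 with an estimated correlation), with periostin (Postn) at 467 ± 154 against 3337 ± 821 CPM and Thbs2 at log2 -3.12. Cell cycle fell in 4 of 18 (4 adjusted over the list alone; 0.00287, and 0.647 with an estimated correlation), with Ccna2 at log2 -2.77. Glycolysis and hypoxia fell in 8 of 17 with Egln3 higher (9 and 1 adjusted over the list alone; 0.00579, and 0.647 with an estimated correlation), with Pgk1 at log2 -1.68. The contractile list did not pass (adjusted p = 0.0988), though Acta2 fell from 996 ± 466 to 299 ± 293 CPM (-1.64, adjusted p = 0.0254). Unnamed cluster 14, with Tagln and Acta2 among its leading genes, lay outside the class. It held 182 cells of metastases, 148 of them from Met replicate 1, and 73 of 4W tumours, so these contractile results do not cover those cells. Resting fibroblast (0.535), inflammatory (0.111), complement (0.0909), basement membrane (0.205), MHC class I presentation (0.205), MHC class II (0.205), interferon response (0.163), protein folding (0.535), matrix proteases and inhibitors (0.203), lipid and adipogenic (0.261) and growth factor lists (0.896) did not pass either. Of the study markers, Thy1 (-2.49), Fap (-1.60), Ly6c1 (-1.40), Pdpn (-1.39) and S100a4 (-1.29) fell, and Cav1 (1.71), Pdgfra (1.04) and Pdgfrb (0.91) rose. Skeletal muscle markers Acta1, Ckm and Des rose beside these groups (3 of 3, with a list adjusted p of 0.0374, and of 0.216 with an estimated correlation), and Wfdc2 fell. All 13 skeletal muscle-like cells of metastases came from Met replicate 3, and Des is also a fixed pericyte or smooth muscle marker.

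**Figure D4:**
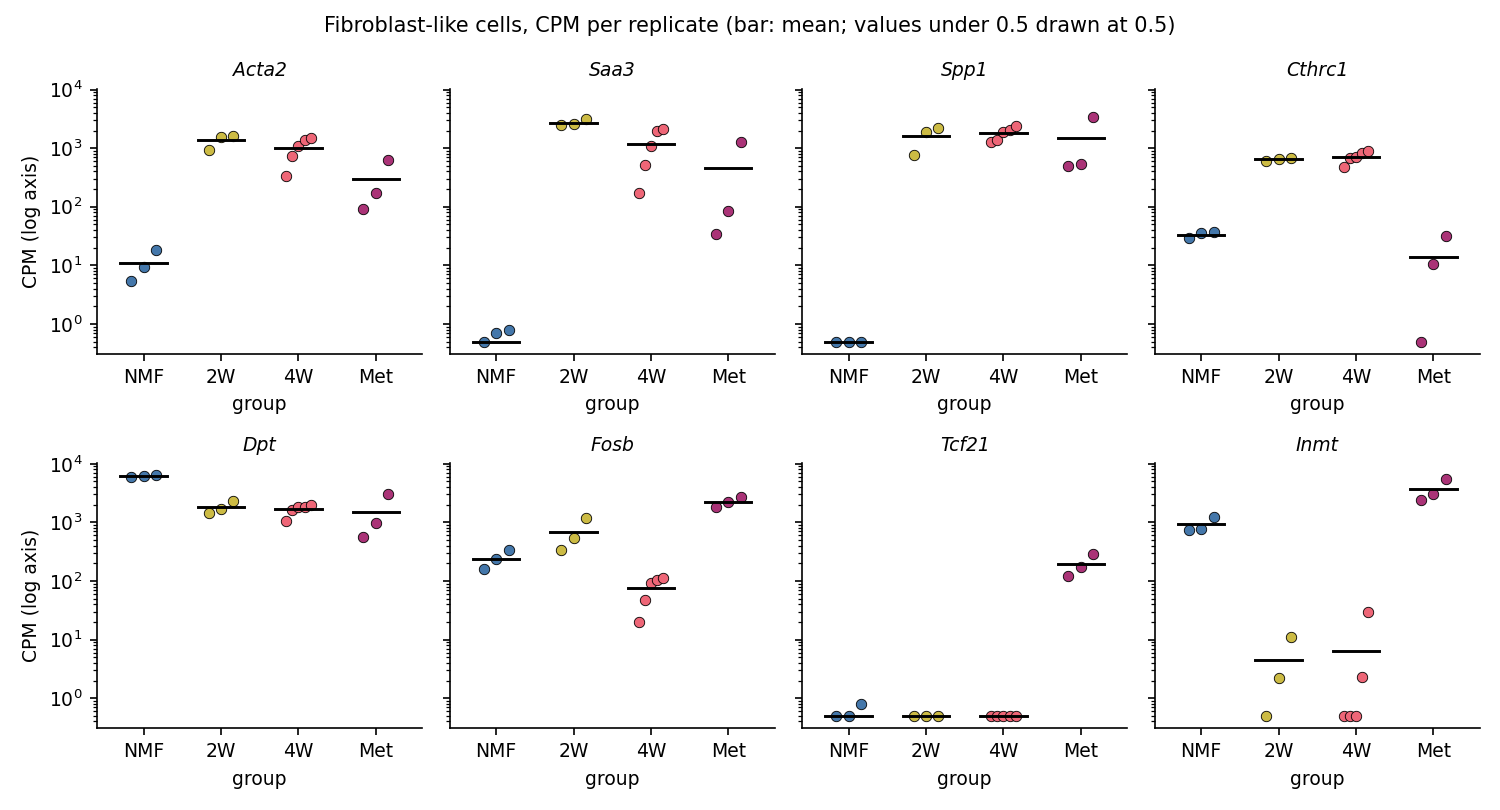
CPM (TMM-scaled, log axis; values under 0.5 drawn at 0.5) of 8 genes in the fibroblast-like class per replicate, by group; points are replicates and bars the means. Acta2 is at 11.1 CPM in fat pad and 1357 at 2W, Fosb lower at 4W (74.8) than at 2W (684) or in metastases (2271), and Tcf21 at 198 in metastases against 0 at 4W.

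Of 10057 genes, edgeR called 803 higher and 612 lower in metastases, and 778 in all with only these groups fitted. Without Met replicate 1 they were 651 higher and 793 lower. The cell cycle (adjusted p = 0.0548) and glycolysis (0.0605) lists lost their calls without Met replicate 3, and 8 lists passed without Met replicate 2, against 5. Among the markers, Acta2 lost its call without Met replicate 2 (log2 change -1.48), Met replicate 3 (-1.17) or 4W replicate 5 (-1.48). S100a4 (-1.02) and Cav1 (0.80) lost theirs without Met replicate 3, Fap (-0.83) and Pdgfrb (0.83) without Met replicate 1, and Pdgfra (0.76) without Met replicate 2. Cluster 10 held the class in metastases, and tissue, enzymes, mouse age, earlier surgery and sequencing batch all differ from 4W and cannot be told apart.

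Summed over all kept cells, the sorted fraction as a whole mixed these changes within fibroblasts with the change in make-up. Spp1 reached 1879 ± 549 CPM at 2W and 3483 ± 911 at 4W with no count in fat pad, and the keratin Krt8 360 ± 31.6 at 2W (at least 494-fold) and 754 ± 203 at 4W (at least 1257-fold). Wnt7b, Padi4 and Plcg2 had no count in fat pad and 193 ± 26.4, 179 ± 52.0 and 158 ± 62.0 CPM at 4W. From 2W to 4W, Fosb fell from 489 ± 328 to 27.4 ± 10.6 CPM (log2 change -4.14), Cxcl1 from 513 ± 356 to 31.1 ± 14.6 (-4.02) and the hyaluronan synthase Has1 from 103 ± 81.7 to 6.69 ± 5.02 (-3.87). The endothelial genes Gpihbp1 (3.45) and Cd93 (3.41) and the stress gene Gadd45a (2.22) rose. Thy1 (-2.38), Fap (-2.23), Pdpn (-2.14), Ly6c1 (-2.28) and Pdgfra (-1.39) fell, and S100a4 stood at 1337 ± 431 against 1175 ± 258 CPM (edgeR adjusted p = 0.826). Pdpn lost its call with each 2W replicate left out in turn, without 4W replicate 1, 2, 3, 4 or 6, within the shared batch and without the top 1% of wells. Gpihbp1, Cd93 and Gadd45a lost theirs without 2W replicate 1 or 3, and Fap and Pdgfra without 2W replicate 3. In metastases Fosb (1248 ± 203 against 27.4 ± 10.6 CPM), Nr4a3, Hopx, Fmo2 and Inmt rose against 4W, as did the marker Ly6c1 (1.48). The growth factor Pdgfc (-2.14), Igfbp3 (-1.84), the hypoxia-induced carbonic anhydrase Car9 (-1.68), the ribosomal Rpl19 (-1.67), counted under a symbol with many pseudogenes, and Slpi (-1.65) fell. Rpl19, Igfbp3 and Ly6c1 lost their calls without Met replicate 3, and Car9 without Met replicate 2 or 3 or 4W replicate 2, 3, 4, 5 or 6. With only these groups fitted all 4 lost theirs.

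MHC class II genes rose in 7 of 7 at 2W and at 4W against fat pad (adjusted p = 7.32e-05 and 4.04e-05, and 0.257 and 0.301 with an estimated correlation). Cell cycle genes rose in 18 of 19 in both (5.26e-10 and 7.69e-07, and 0.257 and 0.301 with an estimated correlation). From 2W to 4W fibrillar and interstitial matrix fell in 18 of 21 (6.82e-10, and 0.321 with an estimated correlation) and matrix proteases and inhibitors in 12 of 16 (1.58e-09, and 0.143 with an estimated correlation). In metastases dissociation stress genes rose in 15 of 17 (4.49e-23, and 0.055 with an estimated correlation) and lung fibroblast genes in 8 of 12 (9.18e-08, and 0.19 with an estimated correlation).

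Of 12700 genes, edgeR called 2302 higher and 1838 lower at 2W against fat pad, 3119 and 2805 at 4W against fat pad, 613 and 1050 at 4W against 2W, and 611 and 260 in metastases against 4W. The count of 1663 for 4W against 2W was 468 without 2W replicate 3, 694 without 2W replicate 2, 1022 without 4W replicate 3 and 1108 without 4W replicate 4. The count of 871 for metastases was 410 without Met replicate 3, 544 without 4W replicate 3, 546 without 4W replicate 6, 1392 without 4W replicate 1, 375 with only these groups fitted and 1323 with DESeq2. Without Met replicate 1, 458 were higher and 475 lower, and without Met replicate 3, 348 and 62; for 4W against fat pad, 2484 and 2575 without NMF replicate 3.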

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

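Of 36 sets of 4W values, 6 held a replicate far from the others by a Dixon test that lets through about 1 set in 20 by chance. Replicate 1 of 4W held 3.36% immune-like cells (next highest 0.315%), 0.504% erythroid-like (0.152%), 0.840% skeletal muscle-like (0.303%) and 11.6% unnamed cells (0.455%). Its Cav1 level over all cells was 297 CPM, with 142 in the next replicate. Thy1 in the fibroblast-like class was 1140 CPM in replicate 2 of 4W, against 1493 in the nearest. Replicate 1 of 4W came from a sequencing batch of its own and had no fibroblast-like sum large enough to test. All values were kept.

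Of the 200 wells that the labels give as holding no cell, 4 had at least 500 UMIs, all in replicate 1 of fat pad, with up to 3484. They were left out of every analysis, and what they hold was not analysed here.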

How the results depend on the processing

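Each choice was changed in turn. Fibroblast-like genes for 4W against 2W numbered 182 with no filter on low counts, 70 with only these groups fitted, 59 with DESeq2 and 20 within the shared sequencing batch, which equals leaving out 4W replicate 2 (20), against 37; with 1 replicate left out the highest was 48, without 4W replicate 5. For 2W against fat pad, 1744 genes passed without 2W replicate 2 and 2737 without clusters seen in 1 replicate, against 2795. For metastases against 4W, 778 passed with only these groups fitted, against 1415; 9 lists passed at 1000 UMIs per well, 8 without Met replicate 2 and 4 without Met replicate 3, against 5. Over all cells 4W against 2W gave 468 genes without 2W replicate 3 and 1856 without 4W replicate 1, against 1663. Metastases against 4W gave 375 with only these groups fitted, 1323 with DESeq2, 410 without Met replicate 3 and 1392 without 4W replicate 1, against 871. In the carcinoma-like class 4W against 2W gave 529 with DESeq2, 37 without 2W replicate 2 and 375 without 4W replicate 5, against 293. Metastases against 4W gave 785 with DESeq2, 175 without Met replicate 2 and 781 without Met replicate 1, against 475. The ratio of S100a4 to Pdpn for 4W against 2W turned to -0.0761 in the fibroblast-like class alone. The lipid and adipogenic list turned upward (adjusted p = 0.84) with the top 1% of wells left out.

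Treating equal replicate numbers as pairs gave 1708 fibroblast-like genes for 4W against fat pad, 6 genes and 3 lists for 4W against 2W and 740 genes for metastases, 137 and 141 genes over all cells, and 54 and 94 in the carcinoma-like class. Among the genes named for all cells in 4W against 2W, Thy1, Has1 and Plcg2 lost their calls in this setting alone, as did Pdgfc in metastases against 4W and, in fibroblast-like cells for 4W against 2W, Btg2, Cxcl12 and Nfkbia, and Fap for 4W against fat pad. Lists that lost theirs were complement (adjusted p = 0.367), lipid and adipogenic (0.233) and MHC class I presentation (0.0529) for 4W against 2W and interferon response (0.0549) for 4W against fat pad. Share differences were then -76.1 and -50.0 points, ratios 5.78 and 2.14, and intensities -4628 and -10814, where the smallest possible exact p is 0.25 or 0.5. Deviations of equal numbers correlated above 0.1 in 0 of 15 pairs in fibroblast-like cells and 1 of 18 over all cells, so the pairing is not borne out by the data. The mitochondrial limit removed no well and gave no different value. The analysis without keratin-bearing cells and that without clusters of 1 replicate were chosen after seeing the data.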

Other observations

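The carcinoma-like class was compared between groups after the classes had been seen, so this test was chosen after seeing the data. From 2W to 4W matrix proteases and inhibitors fell in 7 of 16 members (8 adjusted over the list alone; adjusted p = 1.42e-06, and 0.139 with an estimated correlation). Mmp9 fell from 1432.5 ± 1028 to 113 ± 20.2 CPM (log2 change -3.65, edgeR adjusted p = 0.000106; n = 3 and 6) and Mmp13 from 128 ± 119.5 to 3.72 ± 1.03 (-4.95). Krt14, a basal keratin, fell by 4.83 and Serpina3g by 3.05. Mgp, an inhibitor of calcification, rose from 180.1 ± 52.2 to 1060.2 ± 658 CPM (2.56) and the lysosomal protease Ctsd from 224 ± 27.9 to 606 ± 233 (1.43). Cell cycle genes fell in 9 of 19 members (18 adjusted over the list alone; adjusted p = 1.49e-12, and 0.139 with an estimated correlation) and interferon response genes in 4 of 18 (13 adjusted over the list alone; 2.12e-10, and 0.139 with an estimated correlation). The class came mostly from cluster 4 at 2W (322 cells) and from clusters 0 (1532), 3 (750) and 4 (547) at 4W. Of 10806 genes 97 were higher and 196 lower. The count of 293 was 104, 37 and 60 without 2W replicates 1, 2 and 3, 141 without 4W replicate 3 and 160.0 without 4W replicate 4, and the calls of Mgp and Ctsd ended in some of these. Sparc, at 8529 ± 12666 CPM at 2W, did not hold across replicates either.

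In carcinoma-like cells of metastases against 4W, Fosb (1001 ± 116 against 18.5 ± 6.54 CPM; log2 change 5.71, edgeR adjusted p = 8.8e-10; n = 3 and 6), Nr4a1 (5.38) and Atf3 (5.24) rose. Serpine2, a protease inhibitor, fell from 469.7 ± 221 to 44.6 ± 55.6 CPM (-3.54), and Slpi (-1.85) and Car9 (-2.02) fell; Car9 lost its call without Met replicate 2 or 3. Dissociation stress genes rose in 14 of 16 (15 adjusted over the list alone; adjusted p = 8.87e-25, and 0.0333 with an estimated correlation). Of 10806 genes 292 were higher and 183 lower. In metastases 763 cells of the class lay in cluster 6 and 97 in cluster 22, which held 18 and 0 cells at 4W. Met replicate 2 alone gave 567 cells of cluster 6, and Met replicate 1 gave 91 cells of cluster 22. The count of 475 was 300.0 without 4W replicate 3, 315 without 4W replicate 4, 781, 175 and 183 without Met replicates 1, 2 and 3. Without Met replicate 1, 340 were higher and 441 lower, and without Met replicate 2, 145 and 30. All 125 cells of cluster 20, endothelial-like with Hopx, Car4 and Cldn5, came from metastases, as did 312 of 313 cells of the unnamed cluster 12, with Lyve1, Vwf and Ptprb. Cluster 14, with Tagln, Acta2, Aldh1a2 and Wnt4, held 182 cells of metastases and 73 of 4W tumours. Most came from 1 replicate of each group, 148 from Met replicate 1 and 68 from 4W replicate 1.

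The tests on the carcinoma-like class were chosen after the class was seen. Free carcinoma RNA in wells of fibroblasts cannot make up the class, since 5 fibroblast genes reached at most 4.84% of their fibroblast-like level in it. EpCAM intensity was higher in the class than in fibroblast-like cells in 11 of 11 replicates with a record, which fits carcinoma cells that passed the sort. The ratio of medians ran from 1.10 to 2.85, so the difference was small in some replicates. PDPN and CD45 intensities were lower in the class in 11 of 11. Xist, the RNA of the inactive X chromosome, was lower than in fibroblast-like cells in 10 of 11 replicates (median ratio 0.0304; exact sign test p = 0.0117), but 1.41 times as high in Met replicate 1. The value of Met replicate 1 rests on 22 UMIs in the class and 9 in fibroblast-like cells (Fisher exact p = 0.458). Fibroblast-like cells of fat pad also had little Xist, at 5.87 ± 2.39 CPM. The class lay below all of their replicates in 9 of 11, so Xist alone leaves fibroblasts in another state open. The 5 fibroblast genes argue against that state, at 0.382% to 4.84% of their fibroblast-like level over 11 replicates. Such genes also helped to name the classes, so they are not an independent test.

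The tests on stress genes were chosen after the result was seen. Their median change in carcinoma-like cells was at least 60.1% of that in fibroblast-like cells (-0.94 against -1.57 from 2W to 4W, 2.35 against 2.62 in metastases). Handling between dissociation and lysis would give such a shared change and may explain much of it. Anything else that acts on both classes would give it too, such as the enzymes, which differed for metastases. The test therefore cannot point to handling alone. Sequencing batch cannot be the whole cause for 4W against 2W, since the median within the shared batch was -1.60, with 16 of 17 genes lower (adjusted p = 5.5e-23, and 0.0911 with an estimated correlation).

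The tests of carcinoma RNA in fibroblast-like wells were set before the result, apart from those of MHC class II and S100a4 and a lower limit on counts, added after. The median over 10 members of observed level over keratin-based background was at least 40.1 in every tumour replicate for the contractile list and 46.8 for the inflammatory list, and the ratio for Spp1 at least 4.46. The members used were those called higher than fat pad at both 2W and 4W, so the medians do not cover the whole lists. For these members as a set, background is unlikely to make the rises. Single members went lower in 1 replicate or more, Cxcl5 to 22.1 (highest 2621) and Actg2 to 0 (highest 2762). Outside the 2 lists, Reg1, Reg3g and Ltbp2, also among the largest rises, went to 0 in their lowest replicate. Their highest ratios were 1814, 2837 and 24.05. A ratio of 0 means that the fibroblast-like cells of that replicate had no count of the gene, so it is no sign of background. For 4 MHC class II genes the median ran from 0.686 to 6.74 between replicates, so carcinoma RNA could bring much of this rise and cannot be told apart from expression in fibroblasts. For S100a4 the ratio ran from 1.88 to 7.24 over 8 tumour replicates. Keratin-based background, as estimated here, was below the observed S100a4 level in each of them, though it could bring part of the rise. In 4W replicate 5, at 1.88, the ratio was under the limit of 2 set for these tests. Background and expression in fibroblasts therefore cannot be told apart for S100a4 either.

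Regrouping of replicates was also done after the results were seen. For 2W against fat pad 1 of 10 groupings, the real one, gave 2795 fibroblast-like genes (highest other 0), 13 lists (12) and 4140 genes over all cells (0), but 10 groupings are too few for a share under 0.05. For 4W against fat pad 1 of 56 gave 2684 genes (highest other 245), 2 of 56 gave 14 lists (14) and 1 of 84 gave 5924 genes over all cells (0). For 4W against 2W 1 of 56 gave 37 genes (1), 1 of 84 gave 1663 over all cells (84) and 1 of 84 gave 293 in the carcinoma-like class (13). No other grouping reached these 4W against 2W counts, so chance is unlikely for each taken alone. It is not excluded, since the smallest possible share is 1 of 56 or 1 of 84 and many counts were tried. The 6 lists of 4W against 2W were reached in 6 of 56 groupings (highest 9). The 5 lists of metastases against 4W were reached in 26 of 56 (highest 9), so chance could give as many lists in both contrasts. For metastases against 4W 1 of 56 gave 1415 fibroblast-like genes (209), 1 of 84 gave 475 carcinoma-like genes (238) and 2 of 84 gave 871 over all cells. There the higher count, 964, came from 4W replicate 1 with Met replicates 1 and 3 against the rest.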
